A study of Mus musculus with 4 samples.

How the data were processed

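Total RNA from dorsal skin of C57BL/6J mice aged 8 to 12 weeks was measured on 4 Illumina mouse bead arrays. Per the labels, mice were injected with mini-circle DNA carrying either GFP or IL-17A, and part of the material also received an agent named IMQ. Each array held a pool of 6 mice, so the 4 arrays formed 4 groups of 1 array each: GFP, IL-17A, GFP with IMQ, and IL-17A with IMQ. IMQ is the usual abbreviation of imiquimod, a Toll-like receptor agonist used on mouse skin. The labels gave the abbreviation alone, with no dose, schedule or interval. Per the labels' protocols, RNA was extracted with the QIAGEN RNeasy mini kit, its quality was examined on an Agilent Bioanalyzer, and biotinylated cRNA was made with the Ambion MessageAmp kit. Every array was a pool, so differences between mice were averaged before the measurement and cannot be seen here.

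The deposited table of unnormalized values held 1 linear intensity per probe and array for 45281 probes, without detection p-values, bead numbers or control probes. A background had been subtracted in it: from 32.3% to 33.7% of each array's values were below 0. The program that made these intensities was not given in the sources used here. A second deposited table held the authors' normalized log2 values of the same arrays, with column medians of 4.82, 4.83, 4.83 and 4.83. Its columns ranked probes almost as the intensities of their own array did (Spearman correlation across probes 0.9997 to 0.9999, and at most 0.917 with another array), which bears on the assignment of columns. Among probes with a signal above 1000, the slope of these values on log2 of the own array's signal was 0.980, 1.00, 0.994 and 1.00, close to that of a log2 scale. The authors' normalization method was not given in the sources used here, and the order of probes within an array was not entirely kept.

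The 2 x 2 design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The design planned a background step based on detection p-values or control probes and, where a file held neither, limma's normexp correction with an offset of 50 and quantile normalization. The second route was therefore used, in limma 3.58.1 under R 4.3.3, with log2 taken last. The offset was also to be varied, and this was turned round, to 16 in place of 50. Adding 50 to the signal shrinks the differences of dim genes, and all folds below are on this scale. Probe choice, counts and gene lists were computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.

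A substitute for the detection p-value was chosen after the files had been seen. The values below 0 on an array were mirrored at 0 to describe its noise, and the limit was the signal that a share of 0.01 of this noise would pass. The limits were 12.7, 12.6, 11.6 and 11.8 for GFP, IL-17A, GFP with IMQ and IL-17A with IMQ. They left 20719, 20481, 20535 and 20564 probes above the limit, or 45.2% to 45.8% of each array. The number of arrays, not the number of probes, limits the precision.

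Gene names came from the platform annotation given for the probes. It gave 1 symbol for 34885 probes, several for 18 and none for 10378. Probes with several symbols or none are unnamed here, not without a gene. The Entrez identifiers of 34807 probes were found in a RefSeq gene table, and 0 symbols needed an update. Each gene was represented by the probe with the highest mean among its probes above the limit on at least 1 array, which gave 12729 genes. A gene was counted as higher or lower when the difference was at least 1 on the log2 scale and the brighter array was above its limit. Where the dimmer array was not above its limit, the fold is given as a lower bound, against the higher of that gene's own level and the lowest level above the limit on that array.

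No test was made, because each group has 1 array. No p-value, standard error or confidence interval is given, and the words higher and lower describe these 4 arrays. For each of 29 gene lists, the median difference of its detected members was ranked among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. That percentile describes these arrays and is no test between treatments. Some lists share members and are not separate evidence there. Among them, the neutrophil list shares Chil3 with the macrophage list and Mmp9 with the matrix remodelling list. It shares Elane, Mpo and Prtn3 with the NADPH oxidase and extracellular trap list. The rule for named genes took Il17a, the 8 genes with the largest difference on each side of each comparison, the 5 largest on each side of the difference of differences, and up to 4 detected members of each list with the largest differences. Families of near-identical genes (Sprr2, Lce, Stfa, Krtap, Serpinb3, Defb and the haemoglobins) are given as probe signals that may include a relative's transcript.

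The procedure was tested on simulated data: 4 arrays were drawn from the real probe means and noise, with 200 genes changed in the IL-17A arrays. In the simulated comparison of IL-17A with GFP skin without IMQ, over 12953 genes, 6 of 40 genes raised 2-fold, 34 of 40 raised 4-fold and 40 of 40 raised 8-fold were counted as higher. For genes lowered to 0.5 and 0.25 of their level, 7 of 39 and 25 of 40 were counted. None (0) of 12734 unchanged genes passed, at the assumed noise given below. The changed genes all had a probe above the limit on all 4 arrays, so the recovery does not describe genes dark on an array. A planted list of 20 genes raised 1.5-fold lay at percentile 100, and 2 of 100 unchanged lists lay outside the range from 2.5 to 97.5. The simulation carries technical noise of an assumed size (0.12 on the log2 scale), drawn independently for each probe, and no difference between mice. Members of the real lists may move together, so the 2 of 100 does not show how often such lists would leave the range.

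The alternatives were no background correction, the offset of 16, scaling to the array median, the authors' normalized values, a detection limit at 0.05, no detection filter, detection on all 4 arrays, the mean of a gene's probes, and thresholds of 1.5-fold and 3-fold. Counts without hair shaft genes, meaning members of the hair list and genes with hair keratin or Krtap names, were added after the data had been seen.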

Results

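The data comprised 4 expression profiles of mouse dorsal skin, each from a pool of 6 mice. Mice had been injected with mini-circle DNA, a small circular expression vector, carrying GFP as the control or the cytokine IL-17A. Each was profiled without and with IMQ. The names GFP skin and IL-17A skin give the DNA injected and do not state that the skin held or expressed it. Median probe signals were 8.80 in GFP, 8.31 in IL-17A, 7.85 in GFP with IMQ and 7.96 in IL-17A with IMQ skin. The numbers of genes above the detection limit were 11485, 11523, 11463 and 11532, and 10366 genes were above it on all 4 arrays. No group had a replicate, so every value below describes 1 pooled array per group. The questions were how skin of mice injected with IL-17A DNA differs from control skin and how IMQ-treated skin differs from untreated skin. Another was whether each difference depends on the other treatment.

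The Il17a probe was read first, since the injected DNA carried this gene. Its signal was 11.1 in GFP, 7.98 in IL-17A, 11.01 in GFP with IMQ and 14.4 in IL-17A with IMQ skin. Only the last was above its array's limit, 11.8. Whether this probe detects the transcript of the mini-circle was not known, so it does not check the labels.

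IL-17A skin without IMQ differed from GFP skin in IL-17-responsive, epidermal hyperplasia, hair shaft, macrophage and collagen genes. S100a8 and S100a9, the subunits of calprotectin, were 9.10-fold and 7.18-fold higher in IL-17A skin. Cxcl1, a neutrophil-attracting chemokine, was 7.61-fold higher, and the gap junction gene Gjb2 6.76-fold. Hair keratins were far higher, while the complement genes C1qa and C1qb and the collagen genes Col1a1 and Col1a2 were 2.91-fold, 2.69-fold, 2.44-fold and 2.52-fold lower. Over 12729 genes, 107 were at least 2-fold higher and 126 at least 2-fold lower in IL-17A skin. The authors' values gave 237 and 256, no background correction 359 and 423, median scaling 113 and 112, and a 3-fold threshold 60 and 13.

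IL-17-responsive antimicrobial and cytokine genes were higher as a list: 6 of 21 detected members were at least 2-fold higher and 0 lower, with a median log2 difference of 0.45 at percentile 100 of the random lists. Lcn2, an iron-binding antimicrobial protein, was 4.44-fold higher. Among 26 epidermal hyperplasia genes, 11 were at least 2-fold higher and the median was 0.85, at percentile 100. Krt6b and Krt16, keratins of hyperproliferating epidermis, were 5.62-fold and 4.25-fold higher, and the Sprr2e probe 3.50-fold. Of 40 cornified envelope and barrier genes, 4 were at least 2-fold higher, all from the Lce3 family: the Lce3f, Lce3e, Lce3c and Lce3b probes, at 3.26-fold, 2.92-fold, 2.30-fold and 2.04-fold. The median of that list was 0.11, at percentile 95.4. Basal keratinocyte genes had a median of 0.33 at percentile 99.96 with 0 of 10 at least 2-fold higher, and the 29 cell division genes a median of 0.23, with Cdc20 1.61-fold higher. The matrix gene Tnc, which encodes tenascin C, was 6.70-fold higher, and Timp1, an inhibitor of matrix metalloproteinases, 2.89-fold. These were 2 of 17 matrix remodelling and wound genes, whose median was 0.03.

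Hair shaft and root sheath genes had the largest differences. Krt27 and Krt71, keratins of the inner root sheath, were at least 65.8-fold and at least 54.8-fold higher in IL-17A skin, being below the limit in GFP skin. Krtap7-1, Krtap3-1, Prr9, Krt34, S100a3 and Krt73 were at least 32.6-fold, 22.4-fold, 21.5-fold, 19.4-fold, 18.8-fold and 18.7-fold higher. Of 32 detected members of the list, 23 were at least 2-fold higher and 0 lower. Their median was 2.02, and 2.07 with genes below the limit in GFP skin set at their bound and leaving out 1 gene below the limit on both arrays. Over 4 scaling and background settings the median ran from 2.06 to 4.10. It was 0.51 with detection on all 4 arrays, which removes hair genes dark in GFP skin. The melanocyte list, of 8 genes, moved with them at a median of 0.30 and percentile 99.97 (0.75 with genes at their bound and 3 below the limit on both arrays left out), with Mlana 1.93-fold and Tyrp1 1.73-fold higher. Without 55 hair shaft genes, from the list or with hair keratin or Krtap names, 63 genes in place of 107 were at least 2-fold higher. This setting was chosen after seeing the data, and it left in Prr9, which is outside the list. In 53 of the 107, GFP skin was below the limit.

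Macrophage genes and part of the fibroblast and collagen genes were lower in IL-17A skin. Of 23 monocyte and macrophage genes, 12 were at least 2-fold lower and 0 higher, with a median of -1.16 at percentile 0. Aif1 was 3.00-fold lower and C1qc 2.61-fold. The genes with the largest differences on this side included Siglec1, a sialic acid-binding receptor of macrophages (3.84-fold), the lectin gene Cd209f (3.78-fold), Lyve1 (3.74-fold), Ly86 (3.60-fold) and Wfdc17 (3.46-fold). Akr1cl, Pla1a and Ccn5 were 6.58-fold, 4.11-fold and 3.99-fold lower. The fibroblast and collagen list had 5 of 21 members at least 2-fold lower and a median of -0.54 at percentile 0, with Col5a1 2.59-fold and Ogn 2.23-fold lower. Other dermal and subcutaneous tissue markers lay closer to 0: the medians were -0.04 for 18 endothelial genes, -0.10 for 19 adipocyte genes and -0.06 for 28 skeletal muscle genes. Of these 3 lists, 1 gene, Lyve1, was at least 2-fold lower.

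Other immune lists went in different directions. Among 22 neutrophil genes, 3 were at least 2-fold higher and 1 lower, with a median of 0.17 at percentile 99.8 (0.09 with genes at their bound): the Stfa2 probe was 4.15-fold, Retnlg 3.61-fold and Cxcr2 2.03-fold higher, while Prtn3, a granule protease, was 2.73-fold lower. The list of NADPH oxidase and extracellular trap genes had 3 of 7 members at least 2-fold lower and a median of -0.99 at percentile 0: Prtn3, and the oxidase subunits Cyba (2.42-fold) and Ncf1 (2.16-fold). Type I interferon genes had 5 of 30 at least 2-fold lower and a median of -0.50 at percentile 0, with Oas1g 2.44-fold, Bst2 2.34-fold and Oasl2 2.33-fold lower. Of 17 dendritic and Langerhans cell genes, Clec10a and Cd86 were 2.48-fold and 2.38-fold lower and the median was -0.35 at percentile 0. Of 29 inflammatory cytokine and chemokine genes, Il33 (2.62-fold) and Il1b (2.40-fold) were higher and 3 lower, among them Ccl24 (2.41-fold) and Ccl8 (2.16-fold). No member (0) of the lists of 17 T and NK cell genes, 16 IL-17 receptor pathway genes and 37 autophagy genes was at least 2-fold apart, and the autophagy median was -0.02, at percentile 22.6. Among called genes with a second probe, 19 of 26 higher and 39 of 52 lower genes had a second probe at least 1.5-fold apart in the same direction. With the mean of a gene's probes, Ogn and Oasl2 came under 2-fold, at -0.82 and -0.83 on the log2 scale. The second probe had the opposite sign for Saa1, Nrros and Scamp5. In the other comparisons such second probes were found for 9 of 11 higher and 6 of 10 lower genes (IMQ in GFP skin), 31 of 37 and 9 of 12 (IL-17A under IMQ), and 2 of 6 and 6 of 8 (IMQ in IL-17A skin).

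**Figure D1:**
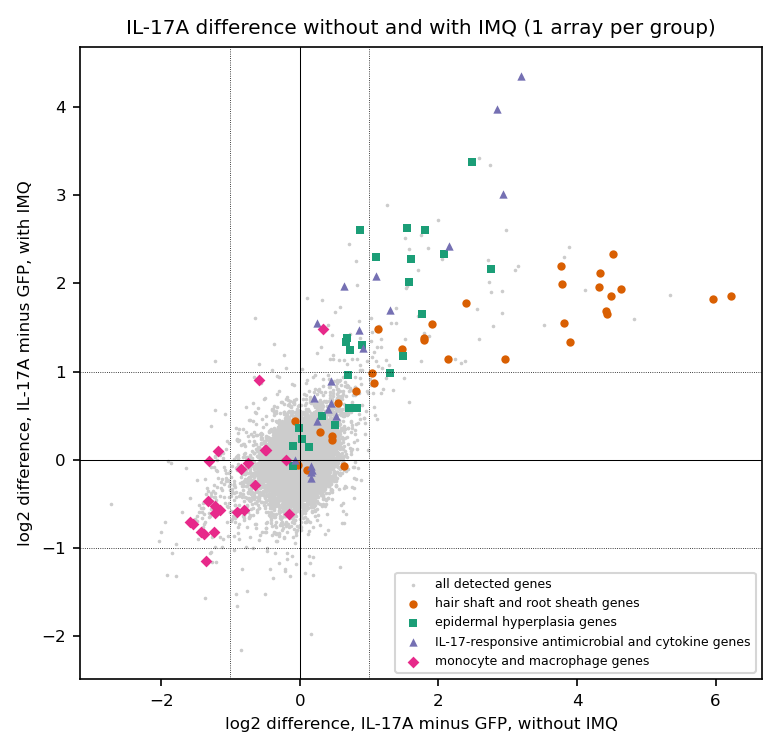
Log2 difference of IL-17A and GFP skin without IMQ (horizontal axis) against that with IMQ (vertical axis), 1 point per gene for 12729 genes, with 4 gene lists coloured and dotted lines at 2-fold. Hair shaft genes lie far to the right, most hyperplasia and IL-17-responsive genes lie in the upper right, and most macrophage genes lie to the left.

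In GFP skin, IMQ-treated skin was set against untreated skin. Hair shaft genes led the genes that were higher with IMQ, and Cd34 and 3 type I interferon genes were among those that were lower. Krt27 and Krt71 were at least 31.8-fold and at least 26.6-fold higher with IMQ. Bst2, an interferon-induced restriction factor, was 2.51-fold lower, and Cd34 2.54-fold lower. In all, 53 genes were at least 2-fold higher and 35 at least 2-fold lower with IMQ, and in 39 of the 53 the untreated skin was below the limit. The excess of higher genes depended on the setting: counts were 50 and 33 with the mean of a gene's probes, 51 and 45 with median scaling, 32 and 3 at 3-fold, 140 and 137 with the authors' values and 82 and 81 with an offset of 16. Lower genes were more numerous with no background correction (263 and 306), at 1.5-fold (197 and 262) and among genes detected on all 4 arrays (14 and 32).

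The hair shaft list had 19 of 32 members at least 2-fold higher with IMQ, a median of 1.34 at percentile 100, and a median of 1.54 with genes at their bound and 2 genes below the limit on both arrays left out. Krtap7-1, Prr9, S100a3, Krt73, Krtap3-1 and Krt34 were at least 16.2-fold, 11.5-fold, 11.2-fold, 10.4-fold, 10.3-fold and 9.64-fold higher. Tyrp1 and Mlana, genes of pigment cells, were 2.07-fold and 2.01-fold higher, 2 of 8 in a list whose median was 0.48 at percentile 100 (0.82 with genes at their bound and 2 below the limit on both arrays left out). Tyrp1 came under 2-fold with the mean of a gene's probes (0.49 on the log2 scale) and Mlana with median scaling (0.98). The epidermal hyperplasia list had 1 of 26 members at least 2-fold higher, Gjb2 at 2.42-fold, and a median of 0.18 at percentile 99.97. None (0) of 21 IL-17-responsive genes was at least 2-fold apart: the median was 0.14 at percentile 99.2 and Lcn2 was at 1.85-fold. Cornified envelope genes had a median of 0.31 at percentile 100, with 0 of 40 at least 2-fold apart. The 25 sebaceous and epidermal lipid genes had a median of 0.27 at percentile 100, with 0 of 25 at least 2-fold apart, and a median of 0.25 in IL-17A against GFP skin without IMQ. Basal keratinocyte genes had a median of 0.28 at percentile 99.92. In IL-17A against GFP skin under IMQ both of these lists had a median of -0.06, inside the random range. Without hair shaft genes, 16 genes in place of 53 were at least 2-fold higher with IMQ.

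Of the genes at least 2-fold lower with IMQ, Akr1cl (3.86-fold), Lyve1 (3.56-fold) and Fosb (3.27-fold) came first, then Greb1, Spon2 and Errfi1 at 2.98-fold, 2.72-fold and 2.55-fold. Pla1a was 2.53-fold lower. Type I interferon genes had 3 of 30 members at least 2-fold lower, Bst2, Oas1g (2.11-fold) and Oasl2 (2.04-fold), and a median of -0.31 at percentile 0. Macrophage genes had a median of -0.62 at percentile 0 with 0 of 23 at least 2-fold apart, and C1qa was at 1.95-fold lower. In the fibroblast and collagen list 1 of 21, Cd34, was at least 2-fold lower, and the median was -0.33 at percentile 0. The mast cell list had a median of -0.41, with Tpsb2 at 1.85-fold and Cpa3 at 1.75-fold lower. Neutrophil genes had a median of -0.08 at percentile 5.61. With the mean of a gene's probes, Oasl2, Spon2 and Gjb2 came under 2-fold, at -0.72, -0.93 and 0.94 on the log2 scale. The GFP array without IMQ stood in this comparison and in that of IL-17A skin, so the 47 genes higher and 24 lower in both share its chance values. The correlation of both differences across genes was 0.77 with a covariance of 0.083, where simulated unchanged arrays sharing 1 control gave 0.50 and 0.015. Sharing a control of equal noise gives 0.50 by construction. The simulated noise came from IMQ in IL-17A skin, the comparison with the smallest spread, so 0.015 may be too low. Averaged over the other treatment, the IL-17A and IMQ differences had a correlation of 0.62, to which a GFP array standing apart would still add. With 1 control array the excess cannot be split, and part of it may come from that array.

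**Figure D2:**
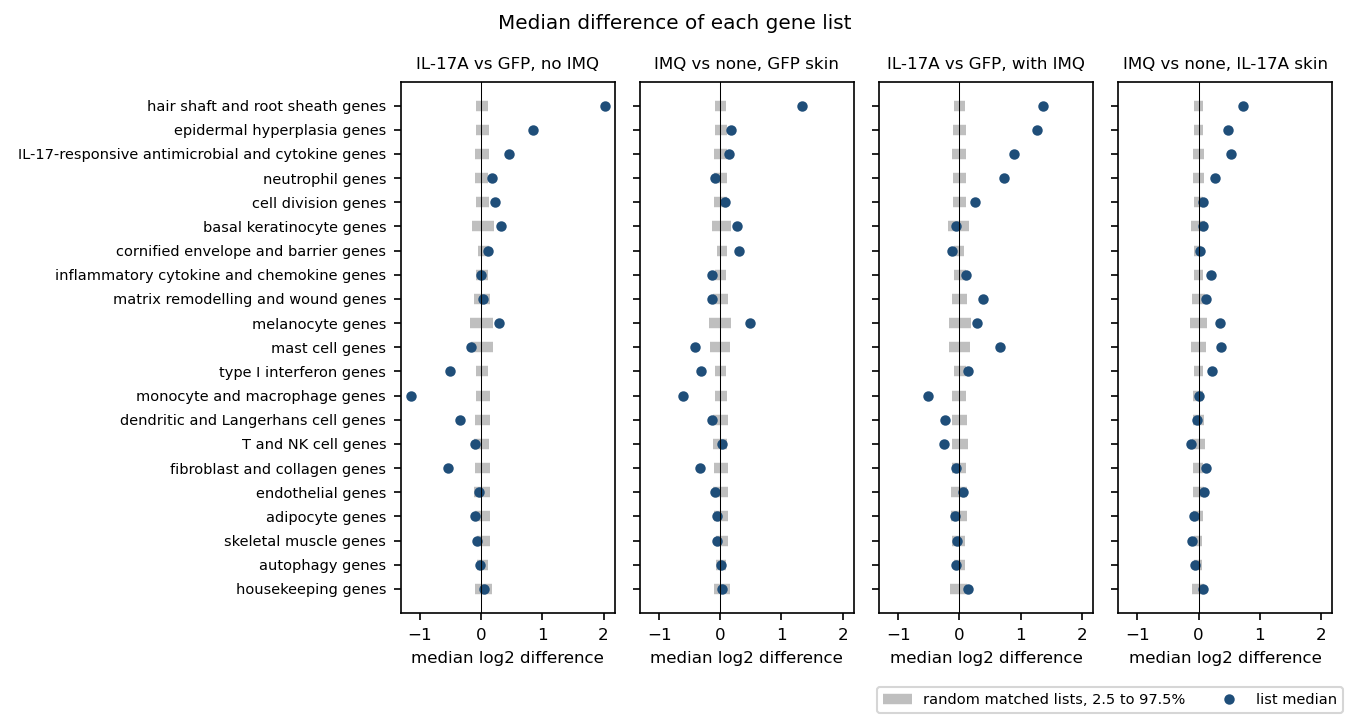
Median log2 difference of 21 gene lists in the 4 comparisons (points), with the central range of the medians of matched random lists (grey bars). Hair shaft genes have the largest median in all 4 comparisons, 2.02, 1.34, 1.37 and 0.73, and macrophage genes the lowest in the first, -1.16.

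Under IMQ, IL-17A skin was set against GFP skin, which asks whether IL-17A makes a difference in treated skin. Members of the IL-17-responsive and hyperplasia lists were much higher in IL-17A skin. S100a8 was 20.5-fold and S100a9 15.8-fold higher, Krt6b 10.4-fold, Tnc 10.2-fold, Cxcl1 8.07-fold and Il1b, an inflammatory cytokine, 7.44-fold. The Csta3 and Gsta4 genes were 10.8-fold and 6.57-fold higher. In all, 135 genes were at least 2-fold higher and 35 at least 2-fold lower in IL-17A skin, and in 13 of the 135 the GFP skin was below the limit. The authors' values gave 252 and 108, and no background correction 401 and 267.

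The IL-17-responsive list had 10 of 21 members at least 2-fold higher, 0 lower and a median of 0.89, and the hyperplasia list 15 of 26, 0 lower and a median of 1.27, both at percentile 100. The Sprr2d, Serpinb3a and Sprr2e probes were 6.17-fold, 6.10-fold and 6.08-fold higher, and Lcn2 5.38-fold. Lce3f, Lce3e and Lce3b were 4.44-fold, 3.92-fold and 3.05-fold higher among 40 cornified envelope genes, whose median was -0.12 at percentile 0.45 (-0.07 with genes at their bound), and Krt77 was 2.18-fold lower. Of 22 neutrophil genes, 7 were at least 2-fold higher and 0 lower, with a median of 0.73 at percentile 100. It was 0.60 with genes at their bound and 1 below the limit on both arrays left out. Retnlg, the Stfa2 probe, the lectin gene Clec4d and the formyl peptide receptor gene Fpr2 were 5.30-fold, 4.86-fold, 4.79-fold and 3.58-fold higher. The NADPH oxidase and extracellular trap list had 0 of 7 at least 2-fold apart and a median of -0.20 at percentile 2.88. Chemokine genes Ccl4 and Ccl7 were 5.46-fold and 3.52-fold higher and Il33 3.29-fold, among 7 of 29 inflammatory genes higher and 1 lower. Tnc, Timp1 (3.86-fold), Mmp13 (2.20-fold) and Mmp9 (2.04-fold) were the 4 of 17 matrix remodelling genes at least 2-fold higher, and that list's median was 0.38 (0.24 with genes at their bound). The histamine-forming enzyme gene Hdc was 3.96-fold and Tpsb2 2.02-fold higher among 10 mast cell genes, with a median of 0.66 at percentile 100. Without IMQ that median was -0.17, and with both treatments against neither it was 0.15 at percentile 92.7, inside the random range. Of the 4 arrays, the mast cell list was lowest on GFP with IMQ, as were the neutrophil, matrix remodelling, and immediate early and heat shock lists. Immediate early and heat shock genes, which also respond to tissue handling, had a median of 0.50 at percentile 100, with 16 of 16 above 0. At least 2-fold higher were 3 of them, Fos (3.32-fold), Fosb (3.06-fold) and Egr1 (2.19-fold).

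Hair shaft genes were higher in IL-17A skin here too, with 21 of 32 at least 2-fold higher and a median of 1.37 at percentile 100, among them the Krtap6-2 probe (5.04-fold), Krt33b (4.61-fold) and Krt33a (4.34-fold). The melanocyte median was 0.28 at percentile 99.9 (0.20 with genes at their bound). On the lower side stood Hamp2 (4.48-fold), the cytochrome P450 gene Cyp2g1, the proteinase inhibitor gene Serpinb6e (3.17-fold) and Inmt (2.96-fold). Cyp2g1 was 3.93-fold lower. Btc, which encodes betacellulin, Ear3, Nnat and Idi2 followed at 2.88-fold, 2.87-fold, 2.82-fold and 2.54-fold. With the mean of a gene's probes, Ear3, Idi2, Lyz2 and Mmp13 came under 2-fold, at -0.72, -0.85, -0.97 and 0.65 on the log2 scale. Macrophage genes had a median of -0.52 at percentile 0, and of 23 genes 1 was at least 2-fold lower, Lyz2 at 2.23-fold, and 1 higher, Chil3 at least 2.34-fold. Chil3 is also on the neutrophil list. Interferon genes had a median of 0.15 at percentile 99.7, with Bst2 2.17-fold higher. Dendritic and Langerhans cell genes had a median of -0.23, and H2-Eb1 and Cd207, the Langerhans cell lectin, were at 1.83-fold and 1.79-fold lower. The T and NK cell median was -0.25 at percentile 0.020, with Cd3g at 1.76-fold lower. Fibroblast and autophagy medians were -0.05 and -0.06, at percentiles 21.5 and 10.5, and cell division genes had a median of 0.25 at percentile 100 with 0 of 29 at least 2-fold apart. For Saa1 the second probe had the opposite sign.

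In IL-17A skin, IMQ-treated skin was set against untreated skin, and the fewest genes were at least 2-fold apart, 21 higher and 10 lower. Among 12729 genes, the authors' values gave 68 and 41, and no background correction 161 and 128. The genes higher with IMQ included members of the hyperplasia and IL-17-responsive lists. The Serpinb3a, Sprr2d and Sprr2e probes were 3.53-fold, 3.23-fold and 2.87-fold higher, S100a8 2.47-fold, Serpinb12 2.47-fold, S100a9 2.42-fold, Ccl4 2.41-fold and Lcn2 2.25-fold. The IL-17-responsive and hyperplasia lists each had 5 members at least 2-fold higher, with medians of 0.53 and 0.48 at percentile 100. Angptl7, Nmrk2 and Pdk4, a kinase that restrains glucose oxidation, were 2.40-fold, 2.40-fold and 2.38-fold lower, and Cyp2g1, Idi2, Nnat, Hamp2 and Ear3 were 2.37-fold, 2.19-fold, 2.19-fold, 2.13-fold and 2.04-fold lower. With the mean of a gene's probes, Ear3, Nmrk2, Idi2 and Angptl7 came under 2-fold, at -0.42, -0.68, -0.81 and -0.97 on the log2 scale, and so did Ccl27a, Ccl4 and Serpinb12, at -0.96, 0.94 and 0.79. Median scaling took Bst2 and Clec4d just under 2-fold, at 0.997 and 0.994, and the authors' values Ccl27a, at -0.98.

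Il1b and the chemokine gene Ccl3 were 2.11-fold and 2.04-fold higher, and Ccl27a, a skin chemokine gene, 2.03-fold lower. Those with Ccl4 were the 3 higher and 1 lower of 29 inflammatory genes, whose median was 0.20. Clec4d, at 2.01-fold, was the 1 of 22 neutrophil genes at least 2-fold higher, and the median was 0.26 at percentile 100. Bst2 was 2.03-fold higher among interferon genes, whose median was 0.21 at percentile 100. Hair shaft genes had a median of 0.73 at percentile 100, with 0 of 32 at least 2-fold apart, and melanocyte genes a median of 0.35. Macrophage genes had a median of 0.01 at percentile 68.2, and collagen genes 0.12. All 21 higher and all 10 lower genes were on the same side in IL-17A against GFP skin under IMQ, which shares the array of both treatments.

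The IL-17A difference was set beside itself without and under IMQ, in pairs that share no array. Of the 107 genes at least 2-fold higher without IMQ, 91 were so under IMQ, where independent lists would share 1.13, and all 107 had the same sign. Part of these shared genes are hair shaft genes: without them 63 in place of 107 and 93 in place of 135 genes were higher. The overlap was not counted without hair shaft genes. Of the 126 lower genes, 9 were at least 2-fold lower under IMQ and 113 had the same sign. Across 12729 genes the correlation of these differences was 0.54 (Spearman 0.31), and genes are not independent replicates. The IMQ differences in GFP and IL-17A skin had a correlation of 0.12 (Spearman 0.01), with 1 higher gene and 0 lower genes in common. That correlation was smaller still without hair shaft genes and with detection on all 4 arrays, as given below. Of the 53 genes higher with IMQ in GFP skin, 52 had the same sign in IL-17A skin, and of the 35 lower genes 15 did. The difference between the IL-17A differences was at least 1 on the log2 scale for 143 genes, 87 positive and 56 negative. That number depended on the processing: it was 342 with an offset of 16, 617 with the authors' values and 1085 with no background correction. On the positive side stood Bst2, Fosb, Akr1cl, Lyve1 and Greb1, at 2.35, 2.26, 2.21, 1.89 and at least 1.64. On the negative side stood Krt27, Krt71, Krtap7-1, Prr9 and Krt73, all below the limit in GFP skin. Their values are therefore bounds, -4.18, -3.95, -3.16, -2.83 and -2.58 or lower. These differences were not tested.

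**Figure D3:**
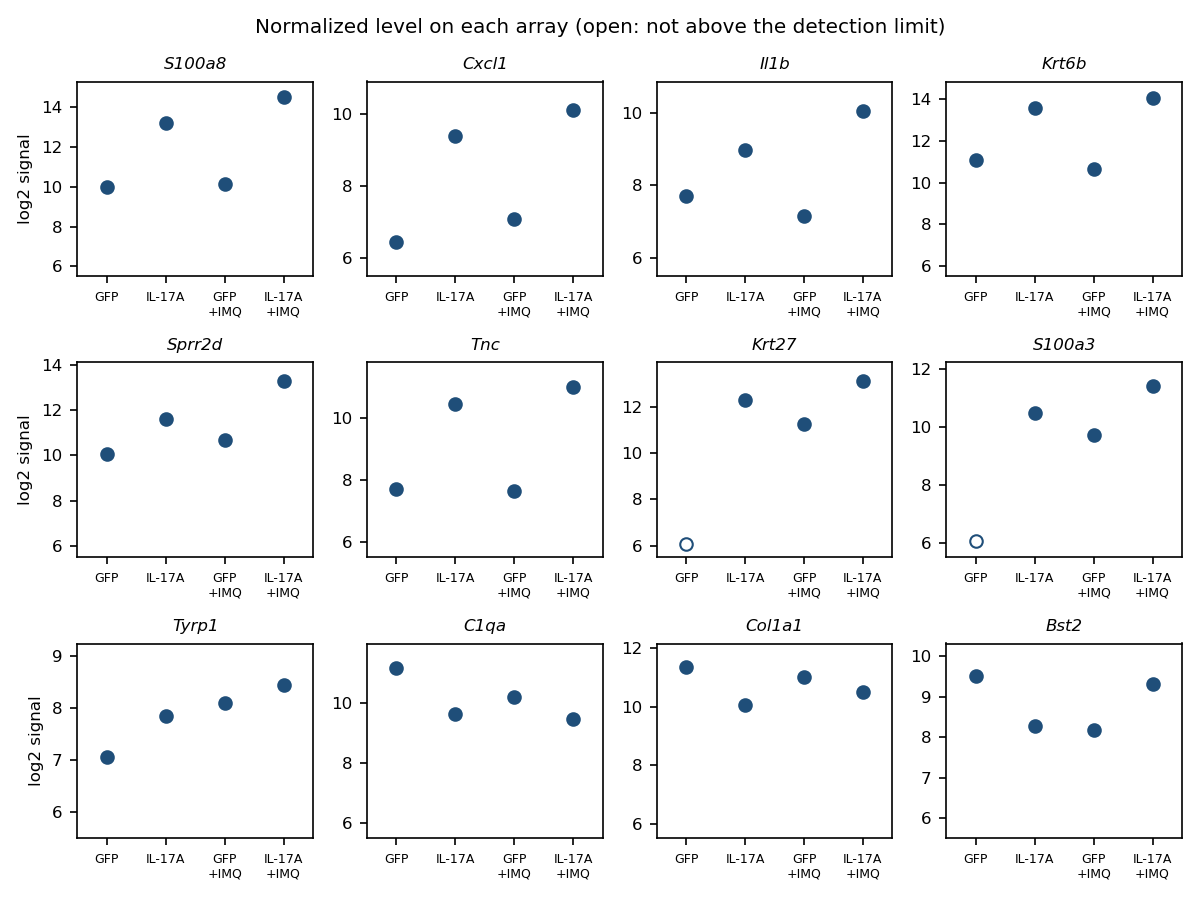
Normalized log2 signal of 12 genes on the 4 arrays, 1 point per pooled array, with open circles where the probe was not above the detection limit. S100a8 lies highest in IL-17A skin with IMQ, at 14.50, and Krt27 is below the limit in GFP skin without IMQ alone.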

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

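The test of hair genes outside the keratin families was set before its result was seen. The tests of melanocyte genes, normalization, interferon genes and labels were chosen only after the results were seen.

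Several gene lists stood on opposite sides of their random lists in GFP and IL-17A skin when IMQ-treated skin was set against untreated skin. The medians in GFP and in IL-17A skin were -0.33 and 0.12 for fibroblast and collagen genes, -0.11 and 0.30 for immediate early and heat shock genes, and -0.14 and 0.20 for inflammatory cytokine and chemokine genes. They were -0.41 and 0.37 for mast cell genes, -0.13 and 0.12 for matrix remodelling genes, and -0.31 and 0.21 for type I interferon genes. The interferon list also had opposite signs for IL-17A against GFP skin, -0.50 without and 0.15 under IMQ. Bst2 was at least 2-fold apart in opposite directions, at -1.23 and 1.12 for IL-17A and at -1.33 and 1.02 for IMQ. With median scaling the last value was 0.997, just under 2-fold. None of these differences between groups was tested, since each rests on 4 arrays, and for each list the contrast between the IMQ differences and that between the IL-17A differences come from the same 4 values.

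Probes without a gene name here, which enter no comparison above, also held signal. At least 2-fold higher were 22 of them in IL-17A against GFP skin without IMQ and 31 under IMQ, and 16 with IMQ in GFP skin and 2 in IL-17A skin. On the lower side there were 17, 12, 3 and 2.

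Hair shaft genes were lower in GFP skin without IMQ than on the other 3 arrays. Those 3 arrays were not level either: under IMQ the median for IL-17A against GFP skin was 1.37 at percentile 100, with 21 of 32 at least 2-fold higher. Cross-hybridisation among keratin probes, as the whole cause, would leave other hair genes in place, but Dsg4, Hoxc13, Msx1 and Padi3 had a median difference of 0.46 between IL-17A and GFP skin, above the random range that ends at 0.22. Normalization was first tested over all planned settings, where the lowest median, 0.51, came from the filter on all 4 arrays. That filter removes hair genes dark in GFP skin and so decides nothing. The test was narrowed after this value had been seen, and the lowest median over 4 scaling and background settings was 2.06. The main offset of 50 shrinks the differences of dim genes, so a smaller offset or no background step could hardly lower the median. The difference was thus present under each of these 4 settings, but the narrowed test does not exclude a part played by normalization. A candidate explanation is more growing follicles in the other 3 pools, where melanocyte genes were above their random range at 0.30, 0.48 and 0.61, but these values share the GFP array and are not 3 separate observations (0.13% of matched random lists were above their range on all 3). In IL-17A against IMQ-treated GFP skin hair genes were higher at 0.64 while melanocyte genes were at -0.11, so this explanation, and whether treatment or the choice of mice set it, stays open.

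Interferon genes were lower with IMQ in GFP skin. A share of macrophages that sets these genes would lower them under IMQ too, where macrophage genes were lower in IL-17A skin, but there the interferon median was 0.15, above its random range. Exchanged labels of the GFP arrays without and with IMQ cannot be told apart from the labels as given. Hyperplasia and IL-17-responsive genes, at medians of 0.18 and 0.14 with IMQ, were both above their random range, against an exchange. Hair shaft and melanocyte genes were above theirs in both skins. Interferon genes lay below theirs in GFP skin and above in IL-17A skin. So did the fibroblast, immediate early, inflammatory, mast cell and matrix lists named above, whose signs would match after an exchange. The time between IMQ and sampling was not given in the sources used here. A late sample, in which an early interferon response has passed, may explain the absence of a rise in GFP skin. Such a sample would not by itself place these genes below untreated skin, and this was not tested.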

How the results depend on the processing

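The setting without hair shaft genes was chosen after seeing the data, and the others were planned. The detection limit at 0.05 and the absence of a filter moved no count, so they say nothing about the stability of the counts. No agreement, list median outside its random range, or value among 146 followed for named genes changed sign (0 reversed) where a setting gave it a value. The 146 values left out list members under 2-fold and the difference of differences. The larger side of a count did turn: for IMQ in GFP skin, 53 higher and 35 lower became more lower than higher with no background correction, at 1.5-fold, with detection on all 4 arrays (14 and 32) and without hair shaft genes (16 and 35). For IL-17A without IMQ, 107 and 126 became 60 and 13 at 3-fold and 113 and 112 with median scaling. Median scaling moved 0 of 116 list medians by more than 0.1, the limit at 0.05 moved 1, the mean of a gene's probes 6, no detection filter 17, the offset of 16 19, detection on all 4 arrays 24, the authors' values 34 and no background correction 40. Where the cause of a shift is not named below, the cause was not tested. Counts are given as higher and lower for IL-17A without IMQ, IMQ in GFP skin, IL-17A under IMQ and IMQ in IL-17A skin, then genes whose combined difference departs from the sum of both treatments by at least 1 in either direction, 143 in the main setting. With no background correction they were 359 and 423, 263 and 306, 401 and 267, 161 and 128, then 1085. The agreement of the IL-17A differences was then 0.42 and that of the main effects 0.50. The share of higher genes went from 60.2% to 46.2% for IMQ in GFP skin, from 79.4% to 60.0% for IL-17A under IMQ and from 67.7% to 55.7% for IMQ in IL-17A skin. The authors' values gave 237 and 256, 140 and 137, 252 and 108, 68 and 41, then 617. The offset of 16 gave 82 and 81 for IMQ in GFP skin, 65 lower for IL-17A under IMQ, 33 higher for IMQ in IL-17A skin, and 342. A smaller offset shrinks the differences of dim genes less. Detection on all 4 arrays removes genes dark on any array, and left 54, 14 and 75 higher genes in the first 3 comparisons, and the agreement of the imiquimod difference in GFP and IL-17A skin was 0.019. The mean of a gene's probes gave 5 lower genes for IMQ in IL-17A skin. It also took 18 of 146 named values under 2-fold, among them Tyrp1 and Gjb2 with IMQ in GFP skin at 0.49 and 0.94 on the log2 scale, while median scaling took 3 (Mlana, Bst2 and Clec4d) and the authors' values 1 (Ccl27a). By construction a threshold of 1.5-fold counts more genes, 271 and 407, 197 and 262, 321 and 236, 123 and 27, then 825, and 3-fold fewer, 60 and 13, 32 and 3, 66 and 3, 2 and 0, then 34. Without hair shaft genes 63 and 16 genes were higher in the first 2 comparisons, and the agreements of the IMQ differences and of the main effects were 0.021 and 0.50, where all genes gave 0.12 and 0.62. Signal over background limits the dim genes: below the limits of 11.6 to 12.7 only bounds can be given. A fit over the 4 arrays with both treatments as terms would leave the interaction as its only error, and was not made.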

Other observations

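The comparison of each treatment alone, that of both with neither, and the tests of explanations in this part were chosen only after the results were seen. The gene lists themselves were set earlier.

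IL-17A skin without IMQ was also set directly against GFP skin with IMQ, a comparison of each treatment alone that was added after seeing the data. In IL-17A skin 57 genes were at least 2-fold higher and 4 lower. S100a8 was 8.30-fold, Krt6b 7.50-fold, Tnc 7.02-fold, Csta3 6.98-fold and S100a9 6.52-fold higher, and Serpinb6e, Ly86, Hamp2 and Wfdc17 were 2.53-fold, 2.10-fold, 2.10-fold and 2.07-fold lower. Hyperplasia genes had 7 of 26 members at least 2-fold higher and a median of 0.73, and neutrophil genes 4 of 22 and a median of 0.34, both at percentile 100. Hair shaft genes had the most members apart, 9 of 32 at least 2-fold higher with a median of 0.64 at percentile 100, while the melanocyte median was -0.11 at percentile 7.89. Macrophage genes had a median of -0.38 at percentile 0, and interferon genes -0.03 at percentile 19.2. With both treatments against neither, 179 genes were at least 2-fold higher and 152 lower.

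Several lists had few members apart. Red blood cell genes had medians of -0.34 with IMQ in GFP skin and -0.25 with IMQ in IL-17A skin, and 0 of 6 were at least 2-fold apart. The clock list had a median of -0.17 for IL-17A under IMQ, with Bhlhe40 1.83-fold higher and Dbp 1.80-fold lower. B and plasma cell genes had medians of -0.05, 0.13, -0.13 and 0.03 in the 4 comparisons, the last -0.09 with genes at their bound and 3 below the limit on both arrays left out. Housekeeping genes had medians of 0.04, 0.03, 0.13 and 0.07, and Gusb was at 1.94-fold lower in IL-17A than in GFP skin without IMQ. The sex-linked list had medians of 0.13, 0.27, -0.01 and 0.06, with Xist and Uty both above the limit, and 0 of 3 at least 2-fold apart.

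Macrophage and collagen genes were lower in IL-17A than in GFP skin without IMQ. A smaller share of dermis and subcutis in the IL-17A piece would lower endothelial, adipocyte and muscle genes by about as much. The lowest of their lower quartiles was -0.20, above the upper quartile of the macrophage list at -0.61. These values speak only to a loss shared by all these layers. Fibroblast and collagen genes had quartiles of -0.89 and -0.38, which overlap those of the macrophage list, -1.32 and -0.61. A smaller share of fibroblast-rich dermis alone therefore stays open. A GFP array that stood apart alone would leave the pair under IMQ level, but macrophage genes had a median of -0.52 there too, though with 1 of 23 at least 2-fold lower where the pair without IMQ had 12 and a median of -1.16, so a part played by the GFP array stays open. For collagen genes that account cannot be told apart from a treatment difference, since their median under IMQ was -0.053, inside the range of random lists. Fewer macrophages, or less of these transcripts in each, may accompany IL-17A in both pairs, and the arrays hold no cell numbers to separate them.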
